A study of Mus musculus with 4 samples.

How the data were processed

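Gene expression was measured in the liver of 3-month-old male mice that carry a mutant Wrn protein, on 4 arrays of Agilent's mouse design with 2 colours. Each array held RNA from 1 mouse that had received 0.4% vitamin C in its drinking water since weaning, labelled with Cy3, and from 1 untreated Wrn mutant mouse, labelled with Cy5, per the labels. The labels call the 4 pairs biological replicates, so 4 treated and 4 untreated livers were compared. The dyes ran the same way on every array: 0 arrays were dye-swapped. A dye effect of a probe can therefore not be told apart from an effect of the treatment. The 4 arrays lay on 1 slide and shared 1 scan date, so no fit with the slide as a block could be made.

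The scanner files hold spot intensity values, which the authors deposited as extracted with Agilent Feature Extraction 10.5.1.1, per the file headers. They give the median signal and the median local background of each spot in each channel, together with Agilent's processed signal and a log10 ratio of Cy5 over Cy3, per the file headers. A table of log2 values of the same arrays was also deposited; the submitters' processing notes name limma without a version, and the steps behind the table are not given in the sources used here. Set against the ratios computed here over 41174 probes, its columns correlated with log2 Cy5 over Cy3 at r = 0.968, 0.950, 0.974 and 0.980 on replicates 1 to 4 (across probes, which are not independent replicates). Its column medians were 0.00374, 0.00497, 0.00225 and 0.00136. The deposited log2 table thus runs as untreated over treated and is centred near 0; its exact scale stayed unknown, with slopes of 1.1 to 1.18 on the ratios computed here. No column of it was left without a sample.

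Ratios were computed as log2 of Cy3 over Cy5, which the dye labels make vitamin C over untreated. The array titles name the treated liver first, whereas the deposited table runs the other way. If the dyes were the reverse of the labels, every direction given here would turn. The background was corrected with normexp (offset 50) on the median signals and median backgrounds, because the files used here give medians where the plan named mean signals. Each array was normalized by loess with control spots at weight 0. Spots flagged as outliers were left out, spots of the same probe were averaged, and arrays were not scaled to each other. R 4.3.3, limma 3.58.1 and statmod 1.5.0 were used, with Python 3.11.15 for the figures. Of 41174 probes, 25097 (61.0%) carried an accession that matched 1 gene symbol in a RefSeq gene table of the mouse assembly GRCm38.p6. The files held no gene symbols, and other probes kept the name in the file. That assembly is not the build named for the array design, so no coordinates are given. A gene was represented by its probe of highest mean intensity, and was kept if that probe was well above background in at least 1 channel on 3 of 4 arrays. This left 31073 genes or accessions, 17082 of them with a symbol.

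Each gene's 4 log ratios were tested against 0 with limma (lmFit and eBayes), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The pairing of livers lies in the array ratio. With 4 arrays, an exact sign-flip test of a single value cannot go below a two-sided p of 0.125, so p-values come from limma's model across genes. Gene lists were tested with camera (inter-gene correlation preset at 0.01), with an estimated correlation and fry beside it; for the fit with a variance trend and the separate-channel fits, camera was run on z-scores of the gene test. Before the data were examined, 42 gene lists, the model, the alternatives and the rule for named genes were fixed. The rule took up to 8 genes in each direction among those past the threshold, with the same sign on all 4 arrays, well above background in both channels on at least 3 arrays and with a settled gene symbol. Where fewer passed, it took those with the smallest unadjusted p. It added the 3 members with the smallest p of each list past the threshold, 1 member of each other list, and Wrn, Gulo, Slc23a1, Slc23a2 and Rgn. A list's median was also placed among the medians of 10000 random lists of genes matched on mean intensity. The first match used 20 bins of intensity; a closer match, to 1 of the 100 genes nearest in intensity, replaced it after the first result had been seen.

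The path from intensities to calls was tested on simulated data: 200 of 31018 genes were changed on 4 arrays, with the spread of the real genes and a smooth dye curve. The test recovered 84.0%, 94.0%, 98.0% and 98.0% of genes changed by 1.5, 2, 3 and 4 times, and 5.29% of its calls were false. It called 1 list where 1 had been shifted. This smooth curve was added after a first simulation with a dye curve bent alike on all 4 arrays, in which 15.9% of gene calls were false and 10 lists were called where 1 had been shifted. Both simulations drew the noise of each gene independently on each array, and changed no gene of the brightest range. They therefore do not give error rates for data in which genes move together or an array departs from the others, as here.

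Alternatives covered the background correction, the normalization within and between arrays, the filter on dim probes, flagged and saturated spots, the probe that stands for a gene, the variance model, the deposited table, separate-channel fits, the threshold, each array left out in turn and other gene set tests. A fit after a running median over mean intensity was taken off was added after the data had been seen. The number of arrays limits the precision. Between 93.7% and 96.7% of the 43379 spots per channel that were not controls were well above background, and 0 spots were saturated.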

Results

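The series asked how vitamin C in the drinking water changes gene expression in the liver of young mice with a mutant Wrn protein, a RecQ helicase that is lost in Werner syndrome. RNA from 4 treated livers was compared with RNA from 4 untreated Wrn mutant livers in 4 pairs, each pair on 1 array. Median spot intensities were 380 to 530 in Cy3 (treated) and 813 to 962 in Cy5 (untreated), against medians of 62 to 67 and 66 to 80 on negative control spots. Repeat spots of a probe differed by an SD of 0.073 to 0.083 in log2 ratio over 245 probes. Values are log2 ratios of vitamin C over untreated, as mean ± SD of 4 arrays. The direction rests on the dye labels and is the opposite of the sign in the deposited log2 table.

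In treated livers, genes of complement and coagulation and genes of growth hormone signalling and male-biased expression were lower as lists, at median log2 ratios of -0.29 each, and genes of NF-kappaB signalling were higher as a list, at 0.19. These calls hold with a preset correlation only: with an estimated correlation 0 lists passed (adjusted p = 0.903 for each of the 3), 0 passed with directional fry, and the NF-kappaB list was also lost without replicate 2. Among members with a log2 intensity under 17, the median was -0.16 over 20 complement and coagulation genes and -0.14 over 16 genes of the growth hormone list. Abundant transcripts such as Ambp, Apoc1 and Sod1 had ratios below 0 on all 4 arrays, and Rnf186, Arpc4 and Smad6 had ratios above 0 on all 4, without passing the test. The same sign on all 4 arrays was a condition for naming these genes. No gene passed the threshold of limma's test in the comparison of treated with untreated livers: 0 of 31073 genes had an adjusted p under 0.05, and the smallest was 0.144. At an unadjusted p under 0.05 there were 8610 genes, 3465 higher and 5145 lower, where chance alone would give 1554. With the sign of replicate 2 turned there were 8428, and 84 to 993 with the other sign flips. The 8610 became 3901, 13561, 3113 and 4110 without replicates 1, 2, 3 and 4. The ratios of 9610 genes (30.9%) had the same sign on all 4 arrays, against 12.5% by chance. A dye effect of a probe would also raise this share and the 8610, as 0 arrays were dye-swapped. The excess over chance is therefore not a measure of the treatment. A rule of unadjusted p under 0.05 with at least a 1.5-fold change took 213 genes, 53 higher and 160 lower. The count depended on the array of replicate 2: without it, 8754 genes passed. It also depended on the fit: 888 genes passed in a separate-channel fit with the array as a random block, and 9634 passed where arrays were centred on the median without loess.

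The rule for named genes required the same sign on all 4 arrays. Among genes higher in treated livers, those it took by smallest p had mean folds of 1.30 to 1.62. None passed the threshold (adjusted p = 0.144 each, limma). Rnf186, a ubiquitin ligase, had the highest mean of these, 0.69 ± 0.15 (SD, n = 4). Arpc4, a subunit of the complex that branches actin, was at 0.51 ± 0.085, Csrp1, a LIM-domain protein, at 0.53 ± 0.11, and Tmsb10, which binds actin monomers, at 0.41 ± 0.047. Rab1b, a GTPase of transport from the endoplasmic reticulum to the Golgi, had a ratio of 0.52 ± 0.12. Smad6, an inhibitor of BMP signalling, had 0.56 ± 0.14, B9d2, a protein of the ciliary base, had 0.45 ± 0.093, and Ubtf, a factor of ribosomal RNA transcription, had 0.37 ± 0.047.

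Among the genes lower in treated livers, those with the smallest p were mostly abundant liver transcripts, and again none passed (adjusted p = 0.144 each, limma). Ambp, which encodes the precursor of bikunin, had a fold of 0.537 and a log2 ratio of -0.90 ± 0.19 (SD, n = 4). The apolipoprotein gene Apoc1 stood at -0.68 ± 0.13, Cox6a1, a subunit of cytochrome c oxidase, at -0.58 ± 0.080, and Sod1, the copper-zinc superoxide dismutase, at -0.52 ± 0.079. F2, which encodes prothrombin, was at -0.48 ± 0.049, and Apoh, a plasma glycoprotein, at -0.45 ± 0.032. These 6 genes had mean log2 intensities of 17.7 to 18.1. Of the 153 genes at a log2 intensity of 17 or more, 65.4% were below 0 on all 4 arrays, with a median of -0.30, and the array medians ran from -0.32 to -0.27. The remaining 2 were the olfactory receptor gene Olfr430, at -0.51 ± 0.067, and Dcaf12l2, at -0.45 ± 0.034. Receptor genes of smell, pheromones and taste, 1012 in number, shared their ratios between replicates 1, 3 and 4 more closely (mean r = 0.889) than genes of like intensity (r of 0.649 to 0.759 in 95% of draws).

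**Figure D1:**
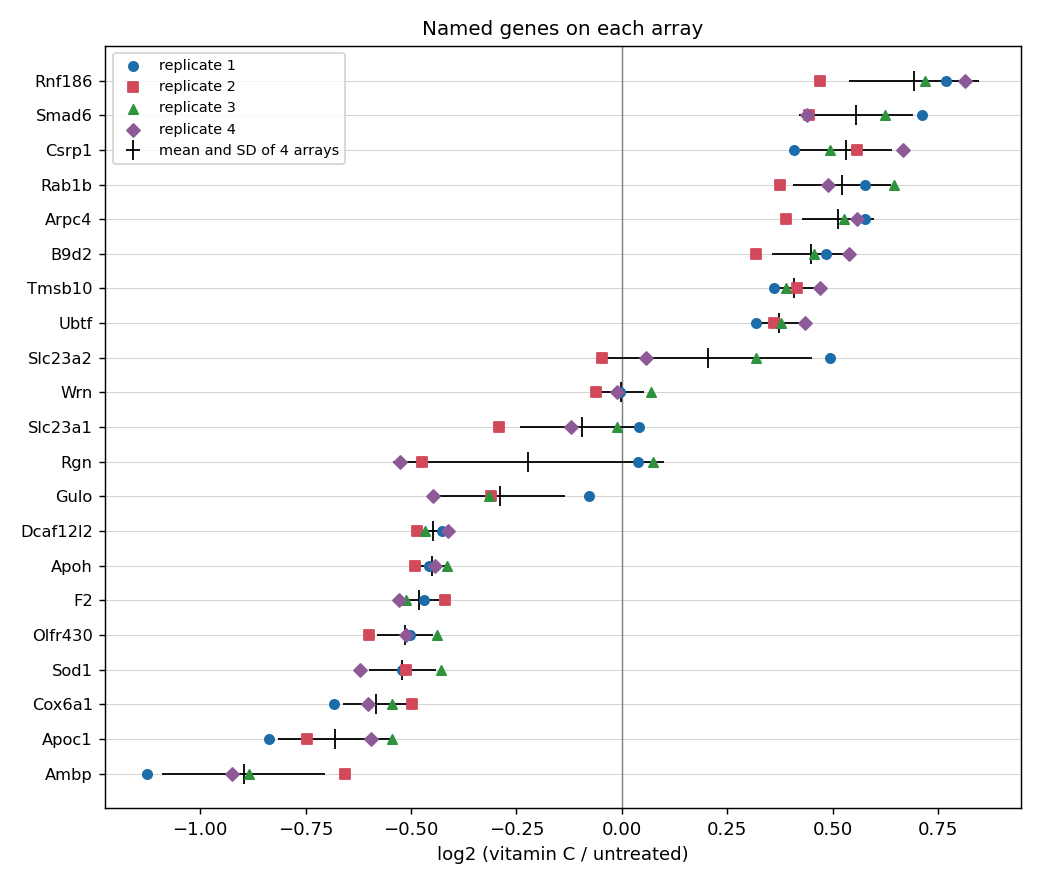
Each row is a named gene; symbols give its log2 ratio of vitamin C over untreated on each of the 4 arrays, and the black mark and bar give the mean and SD. The 8 genes at the top lie above 0 and the 8 at the bottom below 0 on every array, as the rule for naming them required. Slc23a2, Wrn, Slc23a1 and Rgn, named whatever their result, have arrays on both sides.

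Gulo, which encodes the enzyme of the last step of ascorbate synthesis in mice, was at -0.29 ± 0.15 (SD, n = 4) and lower on all 4 arrays, a fold of 0.819 that did not pass over all genes (adjusted p = 0.144, limma). Rgn, which encodes the lactonase of the step before it, was at -0.22 ± 0.32, with 2 arrays on each side of 0, and at 0.073 after a running median over intensity was taken off. The vitamin C transporter genes Slc23a1 and Slc23a2 were at -0.095 ± 0.15 and 0.21 ± 0.25. Wrn was at -0.0015 ± 0.054, and at 0.050 with Agilent's processed signals; both livers of a pair carry the mutant protein, and where its probe lies relative to the mutation was not examined. Of 15 measured genes of vitamin C synthesis, transport and recycling, 4 passed when adjusted over the list alone: Gsto1 (0.30 ± 0.12) and Txnrd2 (0.33 ± 0.20) were higher, and Gulo and the glucose transporter gene Slc2a1 (-0.34 ± 0.17) were lower. The largest mean of the list was that of the glucose transporter gene Slc2a4, at 0.73 ± 1.24, with 0.53, -0.92, 1.94 and 1.37 on replicates 1 to 4, which did not pass. The list's median was 0.11 (camera adjusted p = 0.602), and -0.036 without loess; it was 0.014 without replicate 1 and 0.060 without replicate 3. Of 21 dioxygenases that use ascorbate, the list median was -0.0067 (adjusted p = 0.957), or 0.011 with Agilent's processed signals, and 4 passed when adjusted over the list alone: Egln3 and Kdm4b higher, P4ha2 and Phyh lower. Over all genes, 8610 of 31073 had an unadjusted p under 0.05 (limma). At that level the vitamin C list had 2 members higher and 3 lower, and the dioxygenases 3 higher and 3 lower. Members that pass over a list alone, here and below, therefore do not by themselves set that list apart.

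Of the 42 gene lists, 3 passed camera's threshold with the preset correlation, and 0 passed with an estimated correlation or with directional fry; fry's mixed test, of change in either direction within a list, passed 22, and 9 had an unadjusted camera p under 0.05. Genes of complement and coagulation, which encode plasma proteins made by hepatocytes, fell as a list: 30 of 33 members had a mean below 0, the median was -0.29 and the adjusted p was 3.44e-07. When adjusted over the list alone, 14 members fell and 0 rose, while 0 passed over all genes. They included F2, the clotting inhibitor gene Serpinc1 (-0.38 ± 0.10), Vtn (vitronectin, -0.55 ± 0.14), the fibrinogen chain gene Fgb (-0.90 ± 0.41) and the complement gene C3 (-0.55 ± 0.29). A further, dimmer probe had 0.25 for C3 and 0.0037 for Serpinc1. Array medians were -0.26, -0.079, -0.43 and -0.25 on replicates 1 to 4. With an estimated correlation the list did not pass (adjusted p = 0.903). Of its members, 13 had a log2 intensity of 17 or more; random lists matched on intensity had medians from -0.20 to -0.013 (95% of lists). The median was -0.13 after a running median over intensity was taken off (a fit chosen after the data had been seen), -0.16 with Agilent's processed signals, -0.45 without loess and -0.17 without replicate 3, and the list passed under each of these.

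The list of growth hormone signalling, STAT5 targets and male-biased liver genes fell with the preset correlation (median -0.29, adjusted p = 0.0121) and did not pass with an estimated one (adjusted p = 0.903). Of 23 members, 21 had a mean below 0, and 0 passed when adjusted over the list alone. A log2 intensity of 17 or more, where the median of all genes was -0.30, was found for 7 members, and the other 16 had a median of -0.14. Ghr, the growth hormone receptor gene, was at -0.25 ± 0.081 (SD, n = 4) and at 0.033 with Agilent's processed signals, Nudt7 at -0.55 ± 0.38 and the major urinary protein gene Mup4 at -1.14 ± 0.78. Mup genes share most of their sequence, so signals of single members are uncertain. Array medians were -0.36, 0.13, -0.76 and -0.34, so replicate 2 had the opposite sign. The median was -0.16 without replicate 3 and -0.46 without loess.

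Genes of NF-kappaB signalling and inflammatory cytokines rose as a list with the preset correlation (median 0.19, adjusted p = 0.0202), and the call was lost with an estimated one (adjusted p = 0.903). Of 26 members, 18 had a mean above 0, and 5 passed when adjusted over the list alone, all higher. These were the cytokine gene Il1a (0.20 ± 0.037), Nfkb2 (0.39 ± 0.21) and Nfkbia (0.35 ± 0.19), a subunit and an inhibitor of NF-kappaB, the interleukin antagonist gene Il1rn and the kinase gene Prkcd. Tnf and Il6 had means of -0.37 and -0.30 without passing. The list's members had a median log2 intensity of 9.52, near that of all genes tested (9.61). That is below the 10.1 of the receptor genes of smell, pheromones and taste. At this level a signal above background need not be that of the named gene. The array medians were 0.064, 0.093, 0.14 and 0.28. Without replicate 2 the list no longer passed (median 0.19, adjusted p = 0.0714). Its median was 0.13 without replicate 4 and 0.12 without loess. Macrophage markers, which share the tissue with these genes, had array medians of -0.26, 0.24, 0.070 and 0.49, and markers of T and NK cells 0.032, 0.081, 0.14 and 0.098.

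**Figure D2:**
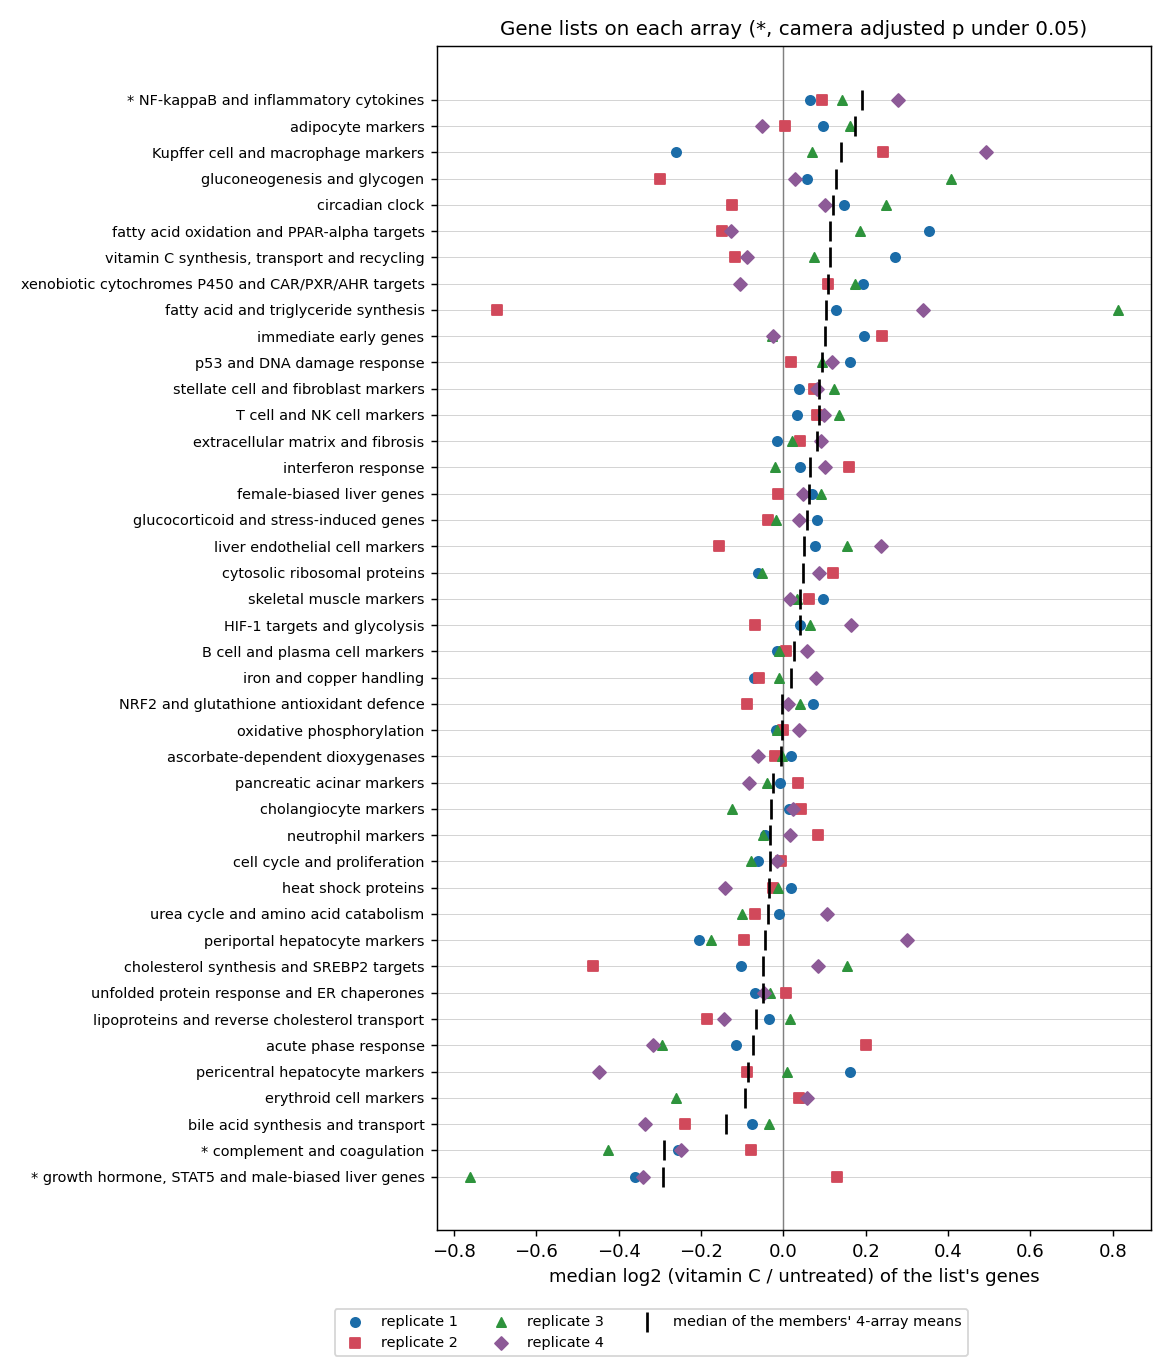
Each row is a gene list; symbols give the median log2 ratio of its members on each array, the black mark the median of the members' means, and a star marks camera's adjusted p under 0.05 with the preset correlation. Complement and coagulation lies below 0 on all 4 arrays, and fatty acid and triglyceride synthesis spreads from -0.70 on replicate 2 to 0.81 on replicate 3.

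The other 39 lists did not pass (camera adjusted p of 0.0561 or more). Fatty acid and triglyceride synthesis had array medians of 0.13, -0.70, 0.81 and 0.34 with a median of 0.10, and Dgat2, of triglyceride synthesis, was its member with the smallest p (-0.30 ± 0.17); the median was 0.40 without replicate 2 and -0.018 without replicate 3. Cholesterol synthesis had a median of -0.048, with -0.46 on replicate 2, and Cyp51 at -0.30 ± 0.10; the median was 0.037 without replicate 2, -0.14 without replicate 3 and -0.10 without replicate 4. Fatty acid oxidation had a median of 0.11, with 1 member, the thiolase gene Acaa2, lower when adjusted over the list alone (-0.50 ± 0.20). The array medians of this list were 0.353, -0.149, 0.186 and -0.127, and its median ran from 0.062 to 0.19 with an array left out. Lipoprotein genes had a median of -0.067 and 5 members lower when adjusted over the list alone (its median was 0.058 after a running median over intensity was taken off), Apoc1, Apoe, Apob, Apoc3 and Apoa2. Bile acid genes had -0.14, or -0.19 to -0.074 with an array left out, with the transporter gene Abcc2 at -0.33 ± 0.10. Gluconeogenesis and glycogen had 0.13, with array medians of 0.057, -0.30, 0.41 and 0.029 and a median of 0.28 without replicate 2 and -0.047 without replicate 3, and Fbp1 had -0.28 ± 0.24. Urea cycle and amino acid catabolism had -0.036, with array medians of -0.012, -0.068, -0.10 and 0.11 and a median of 0.0044 without replicate 2. Xenobiotic cytochromes had a median of 0.11, and Nr1i2, which encodes the receptor PXR, was at 0.50 ± 0.24; the median was -0.038 without replicate 3. Circadian clock genes had 0.12, or -0.0016 without loess, and Cry2, a clock repressor gene, had 0.36 ± 0.18. Female-biased liver genes had a median of 0.061. Acaa2, Dgat2, Fbp1, Apoc1, Apoe, Apoc3 and Apoa2 had log2 intensities of 17 or more, where the median of all genes was -0.30, and Fbp1 had 0.076 after a running median over intensity was taken off. Without loess the medians of fatty acid oxidation (-0.052), fatty acid and triglyceride synthesis (-0.032), gluconeogenesis and glycogen (-0.067) and xenobiotic cytochromes (-0.062) lay below 0. With Agilent's processed signals that of urea cycle and amino acid catabolism (0.054) lay above it. Several of these lists passed in a single setting or a few: without loess, cholesterol synthesis, bile acid, lipoprotein and urea cycle genes were lower, and with Agilent's processed signals, fatty acid oxidation, gluconeogenesis, xenobiotic cytochromes and clock genes were higher. Without replicate 2, fatty acid oxidation, fatty acid and triglyceride synthesis, gluconeogenesis and clock genes passed as higher. Bile acid genes passed as lower without replicate 1, cholesterol synthesis as lower without replicate 3, and fatty acid oxidation and xenobiotic cytochromes as higher without replicate 4.

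Most lists of stress and growth had medians within 0.10 of 0. The p53 and DNA damage list had a median of 0.093 and the smallest adjusted p of the lists that did not pass (0.0561); Bax, a gene of cell death, and Ei24 were higher when adjusted over the list alone (0.29 ± 0.090 and 0.31 ± 0.11). The list passed as higher without replicate 2, 3 or 4 and in the separate-channel fit with the array as a random block. The antioxidant list had a median of -0.0027 with Sod1, Sod2 and Gpx1 lower when adjusted over the list alone, although camera's direction was up. The same holds for oxidative phosphorylation (median -0.0033), where Cox6a1 and Atp5b were lower and Sdhd higher. Ribosomal protein genes had 0.048, with Rps19 at 0.45 ± 0.15, and HIF-1 targets and glycolysis had 0.040, with 5 members higher and 2 lower when adjusted over the list alone, Ldha among the latter (-0.36 ± 0.11), and 0 past over all genes. The medians were -0.050 for the unfolded protein response, -0.035 for heat shock proteins, where the chaperonin gene Hspd1 was at -0.43 ± 0.076, and -0.033 for the cell cycle. The acute phase list had -0.074, with 6 members lower and 2 higher when adjusted over the list alone; the metallothionein genes Mt1 and Mt2 were the 2 higher, and Hp, Fgb and Cp were among the lower. The array medians of this list were -0.116, 0.201, -0.295 and -0.316 on replicates 1 to 4. With an array left out, its median ran from -0.28 to -0.035. Immediate early genes had 0.10, with 15 of 21 members above 0 and 4 higher when adjusted over the list alone, Ier5, Egr1, Jun and Atf3. Glucocorticoid-induced genes had 0.058, iron and copper handling 0.017, the interferon response 0.064, and extracellular matrix and fibrosis 0.082. Trf, the transferrin gene, was at -0.59 ± 0.13; Trf, Ldha, Fgb, Hp, Gpx1, Atp5b, Cox6a1 and Sod1 also had log2 intensities of 17 or more. Oxidative phosphorylation and ribosomal proteins passed in opposite directions in different settings: as lower without loess (-0.18 and -0.16) and as higher with Agilent's processed signals. Ribosomal proteins also passed as higher without replicate 1, without replicate 3 and with a running median over intensity taken off. The unfolded protein response, heat shock and acute phase lists passed as lower without loess, the last of them also without replicate 2. The interferon response and immediate early genes passed as higher with Agilent's processed signals and without replicate 1 or 3, and the immediate early genes also without replicate 4 and with the mean over probes. Without loess, the p53 list (-0.0061), the interferon response (-0.028), immediate early genes (-0.014), HIF-1 targets (-0.033), extracellular matrix (-0.051), glucocorticoid-induced genes (-0.019) and iron and copper handling (-0.24) had medians below 0 without passing. Without replicate 4 the medians of HIF-1 targets (-0.032), iron and copper handling (-0.071) and heat shock proteins (0.0095) changed sign, as did that of heat shock proteins with Agilent's processed signals (0.013). The medians of the antioxidant and oxidative phosphorylation lists lay too near 0 to keep a sign across settings.

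No list of cell type markers passed with all 4 arrays and loess, but some did in other settings, each as higher. Markers of T and NK cells passed with Agilent's processed signals and without replicate 1, macrophage markers without replicate 1, endothelial markers without replicate 2 and adipocyte markers without replicate 4. Medians were 0.14 for Kupffer cells and macrophages, 0.050 for endothelial cells, 0.086 for stellate cells and fibroblasts, 0.085 for T and NK cells, 0.027 for B and plasma cells and -0.032 for neutrophils, for which camera's direction was up. With an array left out, the macrophage median ran from 0.046 to 0.29 and the endothelial median from 0.0042 to 0.14. Of the T and NK cell genes, 5 were higher when adjusted over the list alone, among them Thy1 (0.52 ± 0.20) and Nkg7 (0.60 ± 0.40). Cholangiocyte markers had a median of -0.029; their member Krt23, a keratin gene, had 1.23 ± 0.67, with 0.25 on replicate 2 and 1.40 to 1.75 on the other arrays. Medians were -0.094 for erythroid cells, -0.025 for pancreatic acinar cells, 0.042 for skeletal muscle and 0.17 for adipocytes. Hepatocyte markers had -0.085 for the zone around the central vein and -0.045 for the zone around the portal vein. Their array medians ran from -0.45 to 0.16 and from -0.21 to 0.30; the former list had 0.062 without replicate 4, and the latter 0.020 without replicate 3 and 0.0031 without replicate 1. Without loess, the medians of endothelial cells (-0.032), stellate cells (-0.047) and B and plasma cells (-0.093) lay below 0 and that of neutrophils (0.074) above it, and with Agilent's processed signals those of periportal hepatocyte markers (0.049) and neutrophils (0.079) lay above it. Cholangiocyte markers had 0.024 without replicate 3, and without replicate 4 B and plasma cells had -0.015 and neutrophils 0.0034. Members named outside the rule were chosen after their values had been seen.

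Replicates 1, 3 and 4 shared a pattern from which replicate 2 departed. Across 31061 genes, which are not independent replicates, Pearson's r of the log2 ratios was 0.718 between replicates 1 and 3, 0.601 between 1 and 4 and 0.785 between 3 and 4. It was 0.020, -0.147 and -0.178 between replicate 2 and replicates 1, 3 and 4. Mup1 showed the contrast, with -1.91, 0.25, -3.06 and -2.99 on replicates 1 to 4, as did Cyp4a14, a target of PPAR-alpha, with 3.49, -1.57, 3.92 and 1.43; both were chosen after their values had been seen.

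**Figure D3:**
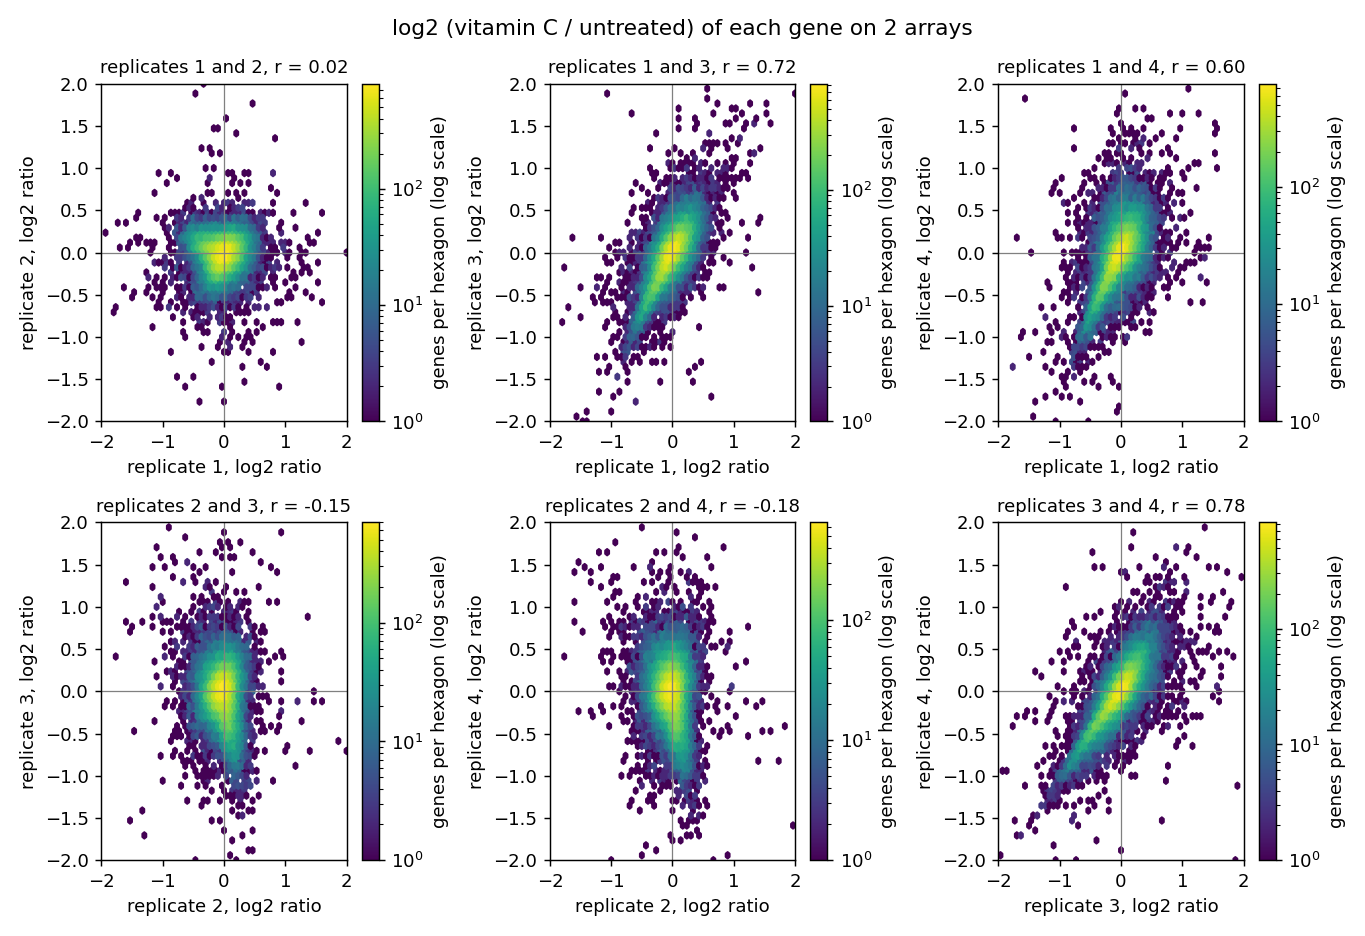
Each panel sets the log2 ratio of vitamin C over untreated on 1 array against that on another, with colour for the number of genes per hexagon on a log scale; axes end at -2 and 2, and the few genes beyond are not drawn. Replicates 1, 3 and 4 follow each other (r = 0.601 to 0.785), with a narrow tail of genes below 0, and replicate 2 follows none of them (r = -0.178 to 0.020).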

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

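No test in this part was chosen after the results were seen. Of 113 values with 4 arrays, 5 had an array far from the other 3 by Dixon's test at 95%, where chance alone gives about 5.6; no pattern is read from them. The log2 ratio of Abcc2 was -0.178 on replicate 1 against -0.405 to -0.369 on the others. Ier5 had 0.431 on replicate 4 against 0.223 to 0.239, and Trf -0.781 on replicate 3 against -0.534 to -0.525. The median of the cholangiocyte markers was -0.124 on replicate 3 against 0.014 to 0.043, and that of the erythroid markers was -0.262 on replicate 3 against 0.039 to 0.058. Replicate 2 was the outlying array in 0 of these. Most named genes among the values were chosen for a small p, some also for the same sign on all 4 arrays. Genes on which an array departs were thus disfavoured, so the 0 and the comparison with chance say little about replicate 2.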

How the results depend on the processing

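The fit with a running median over intensity taken off was chosen after the data had been seen; the other settings were planned. No gene passed with no background correction, an offset of 16, Agilent's processed signals, scaling between arrays, no filter or a strict filter, flagged spots kept, mean or single probes, a variance trend, the deposited table, the running median taken off or separate channels with no replicate block (limma). At an unadjusted p under 0.05 (limma), these settings gave 4466 to 8986 genes, and single probes gave 10698 probes. Leaving out saturated spots moved nothing, as there were 0. Median centring without loess gave 9634 genes, 4346 higher and 5288 lower, and separate channels with the array as a random block gave 888, 555 higher and 333 lower. The rule of unadjusted p and 1.5-fold gave 213, 53 higher and 160 lower. Leaving out each array gave 0 to 8754 genes, 0 to 3119 higher and 0 to 5635 lower; the 8754 came without replicate 2, and the other leave-outs gave 0. The 3 lists became 12 with Agilent's processed signals and 12 without loess, 8 to 9 with an array left out, and 0 with an estimated correlation and 0 with directional fry. Without loess, the medians of oxidative phosphorylation (-0.18) and ribosomal proteins (-0.16) turned lower and passed, while with Agilent's processed signals both lists passed as higher. The causes of these moves were not tested. Complement and the growth hormone list passed in every setting in which lists were tested with camera's preset correlation; the NF-kappaB list was lost without replicate 2. Over these settings, camera's direction of a list turned 52 times and the sign of a named gene 9 times without passing on either side, and 42 list and 149 gene values newly passed. No fit with the slide as a block was run, since the arrays share 1 slide. At least 93.7% of spots were well above background, which does not show that a signal is that of the named gene. Of 1033 receptor genes of smell, pheromones and taste on the array, 1012 were tested in these livers.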

Other observations

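The test of a swap, the feeding-state test, the test of urinary protein signal, the running median and the closer intensity match were chosen after the result had been seen, as were the genes named here outside the rule. Lipid and clock genes had ratios of opposite sign on different arrays. Neither the fatty acid and triglyceride synthesis list nor the clock list passed over the 4 arrays with loess. With Agilent's processed signals the clock list passed as higher. The fatty acid and triglyceride synthesis genes Fasn, Scd1 and Pnpla3 had log2 ratios of -2.06, -1.76 and -1.77 on replicate 2. On replicate 3 they had 1.66, 0.43 and 2.16. The list's median lay at the 99.7, 0, 100 and 100 percentile of intensity-matched random lists on replicates 1 to 4, and that of the circadian clock list at the 99.9, 0.28, 100 and 96.1 percentile. Percentiles among random lists do not allow for correlation within a list, estimated at 0.49 and 0.14 for these lists. Cholesterol synthesis was at the 0 percentile on replicate 2 and the 99.6 percentile on replicate 3. Cyp2b9 was above 0 on all 4 arrays, with log2 ratios of 1.58, 0.49, 3.34 and 0.97, and Igfbp1 had log2 ratios of 1.60, -0.61, 1.54 and 1.49.

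Replicate 2 stood apart from replicates 1, 3 and 4. A swap of dyes or tubes would give a slope near -1 if the ratios of replicate 2 were as large as those on the other arrays. Over 104 genes with a mean of at least 1 in size on the other arrays, its slope was -0.20 (95% bootstrap interval -0.27 to -0.12). This argues against a swap with ratios of that size. The interval resamples genes, which are not independent. A swap with weaker ratios was not tested: the SD of log2 ratios over genes was 0.17 on replicate 2 and 0.22 to 0.31 on the others. Noise between spots is argued against by the spread of repeat spots, 0.0772 on replicate 2 within 0.0732 to 0.0831 on the others. Repeat spots share the RNA and labelling of their array, so poor RNA or labelling was not tested. Feeding state or time of day at collection stays open as a candidate explanation: the synthesis list was at the 0 percentile on replicate 2 and above the 99 percentile on the others. This test used the synthesis list alone, and the contrast was not particular to it. Fatty acid oxidation lay at the 100, 0.02, 100 and 2.99 percentile on replicates 1 to 4. The growth hormone list lay at the 0, 100, 0 and 0.01 percentile. The test can therefore not tell feeding state from another cause that moves many lists. A difference between treated pairs in their response to vitamin C also stays open and was not tested.

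The complement and coagulation list was lower on all 4 arrays. Whether a leftover intensity trend is the whole cause stays open. The list's median lay at the 0 to 0.02 percentile of matched lists in different draws. Taking off a running median moved it from -0.29 to -0.13, still below 0. The percentiles do not allow for correlation within the list, estimated at 0.24. On replicate 2 alone the median lay inside the matched range. A dye effect tied to single probes may contribute: in 8 genes with a further probe, the further probes had a median of -0.029 (95% bootstrap interval -0.17 to 0.066) against -0.33 on the main probes. The further probes were dimmer than the main ones, so this cannot tell a dye effect of single probes from an intensity trend. A dye effect tied to the transcript cannot be told apart from treatment, because 0 arrays were dye-swapped.

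Genes of smell, pheromone and taste receptors, which act mainly in sensory tissue, shared the ratios of replicates 1, 3 and 4. They did not share those of replicate 2, whose mean r with replicates 1, 3 and 4 over these genes was -0.323. Their 1012 members had a median log2 intensity of 10.1, against 9.61 for all genes tested, and a mean r of 0.889 between these arrays; that is the 100 percentile of intensity-matched draws, whose 95% range was 0.649 to 0.759. Signal from other transcripts on these probes is consistent with this value and stays open, although the share of receptor genes with a mean ratio of at least 1.5-fold, 0.395%, was below the median of the matched draws, 0.791%. Major urinary protein transcripts as its source also stay open. This was examined over the 829 receptor genes below 0 on replicate 1. Their measured ratios on replicate 3 had a slope of 1.06 on those predicted from replicate 1 and Mup1 (95% bootstrap interval 1.01 to 1.1). The interval missed the slope of 1 set for a fit, by too little to decide. The model takes the Mup1 ratio at face value and so excludes nothing. Without replicate 2, 45.8% of receptor genes passed the threshold, against 28.2% of all genes, so the 8754 calls without that array hold many probes whose ratio may not be that of their gene.

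Different probes of a gene gave weakly related ratios. Over 5882 genes with a further probe, the mean log2 ratios of the probes correlated at r = 0.247, and on single arrays at 0.235 to 0.376. Of the 8754 genes, 58.3% had the other sign on replicate 2.

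The 4 arrays allow 8 sign flips, too few for a share under 0.05. For genes, 8 of 8 flips gave at least the real count of 0, and the highest other was 0. Any flip reaches a count of 0, so this comparison decides nothing. At an unadjusted p under 0.05 (limma), the real 8610 compare with 8428 with replicate 2 turned and at most 993 with other flips. For lists, 8 of 8 gave at least the real count of 3, and the highest other was 20, with replicates 2 and 4 turned. Flips that call several times the real count point to a structure of the samples, such as genes of a list that move together on single arrays: estimated correlations within lists reached 0.73, against the 0.01 preset.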
